A study of Mus musculus with 10 samples.

How the data were processed

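The study measured RNA from whole thyroid of male mice of the C57BL/6J strain whose Retsat alleles were floxed, either carrying Cre (knockout, 5 libraries) or lacking it (control, 5 libraries). Per the labels' protocols, RNA was purified on columns, treated with DNase and made into libraries with the NEBNext Ultra II RNA kit. Groups and replicate numbers were taken from the sample titles and match the genotype labels. The labels give an age of 22 weeks and a diet of 12 weeks that began at 8 weeks of age, which would end at 20 weeks, and no source used here accounts for the difference.

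The deposited values are whole-number counts of reads per gene, not normalized. Per the submitters' processing notes, reads were trimmed with Trimmomatic and aligned with STAR, whose versions and settings are not given in the sources used here. Per the file headers, the authors counted reads with featureCounts 2.0.1 over exons grouped by gene of the GENCODE M28 annotation, giving each read to the feature with the largest overlap. Per the submitters' processing notes the genome was GRCm39. Per the file headers the counting did not use strand, so reads of overlapping genes on opposite strands cannot be told apart, and no option to count reads with several alignments was set, so near-identical gene copies lose reads or exchange them. Whether reads were single or paired is not given in the sources used here. The files hold 55414 genes. Symbols came from a table of gene names matched on the gene identifier without its version, and 52081 genes had one. Of the 19361 genes tested, 54 had none.

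Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM, dispersions were estimated and the groups were compared with glmQLFit and glmQLFTest. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Standard errors of log2 differences were derived from the quasi-likelihood F statistic. CPM values use the TMM-scaled totals, and log2 CPM values use a prior count of 2. The common dispersion was 0.0861, a biological coefficient of variation of 29.3%. Median standard errors of a log2 difference were 0.35 for genes under 0 log2 CPM, 0.19 from 0 to 3, 0.11 from 3 to 6 and 0.096 over 6, which is the precision that the depth and the spread between libraries gave.

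The test of genes was checked on simulated counts drawn from the real means, dispersions and library sizes of knockout against control (19131 genes run, 50 genes changed at each fold). It recovered 20% of genes changed 1.5-fold, 64% at 2-fold, 76% at 4-fold and 94% at 8-fold, with 7 false calls among 134. All changed genes were in the same simulated set, which makes the adjusted threshold easier to pass. Recovery would be lower where few genes change. The list test, run in the same way on 19117 genes, called a list of 20 genes shifted by 0.5 on the log2 scale and 0 of 20 unchanged lists. Those simulated genes vary independently, which genes in tissue do not.

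Before the data were examined, 38 gene lists were written for thyroid function, vitamin A, metabolism, stress and markers of cell types that a dissected thyroid can hold. Lists with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation 0.01), with an estimated correlation and with fry as alternatives, and the mean log2 CPM of each list was compared by an exact two-sided permutation test over all 252 assignments of the libraries. Intervals of 95% for list means invert that test. The genes named were set before the data were examined as Retsat, up to 12 genes per direction past the threshold, the 10 genes with the smallest p when fewer than 6 passed (predicted genes counted, not named), up to 4 members of each list with the smallest p and any member of the thyroid hormone synthesis, thyroid transcription factor and retinoid lists. Gm15459, Hbp1, Klf15, Rragd, Pik3ip1, Ccng2, Nr1d1, Nr1d2 and Hspa8 were named after their values were seen.

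Alternatives chosen before the data were examined were DESeq2 size factors, library totals alone, no filter beyond 1 count, a mean CPM of at least 1, DESeq2 1.42.0 (Wald test), limma-voom, robust empirical Bayes, the replicate number as a block, each library left out in turn, the means of skeletal muscle or of adipocyte markers as a covariate, and 1 surrogate variable (sva 3.50.0). After the data were seen, fits without the 2 libraries with high Pth counts, without Tg and the mitochondrial genome, and with the mean of the immediate early genes as a covariate were added. Transcripts of Gm15459 were compared with all mouse transcripts of another GENCODE release with BLAST 2.17.0. No library was left out of the comparison, and no 2 libraries of a group agreed within sampling noise (the smallest chi-square per degree of freedom between libraries of a group was 65.7).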

Results

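Thyroid RNA was sequenced from male mice that carried floxed alleles of Retsat, the gene of retinol saturase, an enzyme that acts on the vitamin A alcohol retinol. In the knockout group (5 libraries) the mice also carried a Cre recombinase transgene driven by thyroid peroxidase (TPO) sequences, which directs deletion to the follicular cells that make thyroid hormone. In the control group (5 libraries) the same floxed alleles were present without Cre. All mice had received a high-fat diet for 12 weeks from an age of 8 weeks, and the whole gland was used at 22 weeks. The labels do not say whether each library came from its own animal, so the p-values below measure the spread between these libraries. Each library held between 112417680 and 135085281 counted reads. Thyroglobulin (Tg), the protein on which thyroid hormone is built, took 16.8% to 23.1% of them, and the mitochondrial genome took 2.56% to 5.83%. The comparison asks what loss of retinol saturase does to the thyroid transcriptome. Only the knockout group carried the Cre transgene. Effects of Cre itself or of DNA linked to the transgene therefore cannot be told apart from loss of Retsat.

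Retsat itself was lower in every knockout library than in any control library. It stood at 71.0 ± 6.80 normalised read counts (CPM, counts scaled to a common library size; SD, n = 5) in control and at 38.0 ± 7.28 CPM (SD, n = 5) in knockout, which is 53.5% of the control level. The gene (ENSMUSG00000056666.14) lies on chromosome 6 between positions 72575458 and 72585408 of GRCm39, and the value counts reads over all 3537 bp of its annotated exons. The labels do not name the floxed exons, so a transcript that lost only those would still be counted. The whole gland was used, so cells in which Cre did not act can contribute Retsat reads as well. Counts per gene cannot tell these sources of the remaining reads apart. The control libraries ranged from 66.9 to 83.0 CPM and the knockout libraries from 29.2 to 48.1 CPM. Retsat fell by 0.90 on the log2 scale (SE 0.13, 95% interval -1.18 to -0.63), and an exact two-sided permutation test of the log2 CPM gave p = 0.0079, the smallest that 5 against 5 libraries allow. Judged as the targeted gene on its own, with an unadjusted edgeR p of 1.38e-05, the difference passed the threshold. Adjusted over all genes it did not (edgeR quasi-likelihood, adjusted p = 0.160). With the mean of the immediate early genes as a covariate, an alternative chosen after the data were seen, the log2 difference was -0.60. That mean did not overlap between the groups (3.41 to 3.91 log2 CPM in control, 3.93 to 4.87 in knockout). The covariate can thus take up part of a group difference. A smaller difference or a lost call with it, here or below, cannot decide whether a result is fragile.

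**Figure D1:**
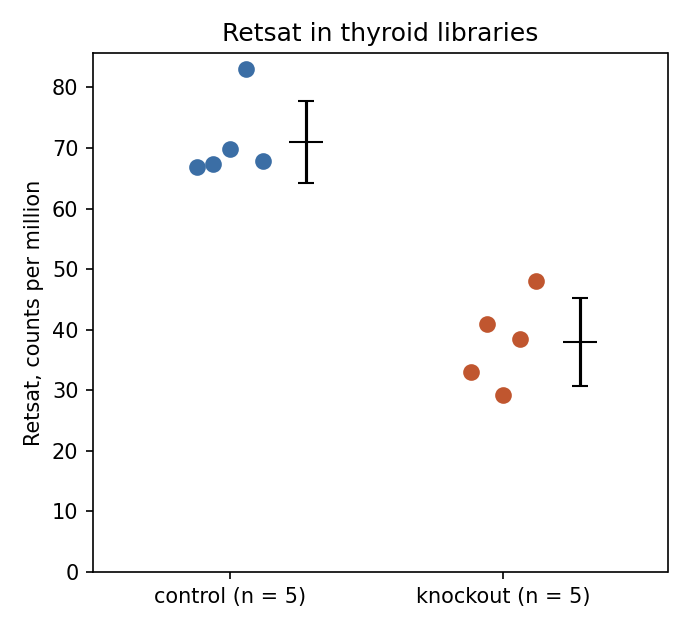
Retsat expression in CPM in each of 5 control and 5 knockout thyroid libraries (points), with the mean and SD of each group (bar and whiskers). The control libraries lie between 66.9 and 83.0 CPM and the knockout libraries between 29.2 and 48.1 CPM, without overlap.

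Beyond Retsat, the genes with the smallest p-values included a general transcription factor subunit, a myeloid receptor and several genes that stood lower in knockout. Gtf2a1, a subunit of the transcription factor TFIIA, was at 38.8 ± 3.57 CPM in control and 73.1 ± 20.7 CPM in knockout (SD, n = 5 each). Trem1, an activating receptor of myeloid cells, was close to the detection limit in both groups, at 0.064 ± 0.021 and 0.431 ± 0.275 CPM. Fnip1, a partner of folliculin in nutrient sensing, was at 61.5 ± 6.93 CPM in control and 39.8 ± 7.0 CPM in knockout. Klhl24, a substrate adaptor of a ubiquitin ligase, was at 136 ± 9.86 and 101 ± 10.3 CPM, and Paip2b, a repressor of translation, at 60.7 ± 2.63 and 48.4 ± 2.91 CPM. The log2 differences were 0.92 (SE 0.17) for Gtf2a1, 2.72 (SE 0.51) for Trem1, -0.63 (SE 0.12) for Fnip1, -0.43 (SE 0.08) for Klhl24 and -0.33 (SE 0.06) for Paip2b. That of Trem1 was 1.76 with the immediate early genes as a covariate. Each of these 5 genes had the same adjusted p of 0.634 with edgeR and did not pass. In these 5 genes the groups did not overlap, which was so for 259 of the 19361 genes tested (1.34%), where chance gives 0.79%. The other 4 of the 10 genes with the smallest p-values were predicted genes or pseudogenes.

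Over all 19361 genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment placed 0 genes past the threshold of 0.05. At an unadjusted p under 0.05 there were 1484 genes, 738 of them higher and 746 lower in knockout, where 968 are expected by chance, and 917 without knockout replicate 1. limma-voom also called 0 genes and DESeq2 called 14 (9 higher and 5 lower), among them Retsat, Gtf2a1, Trem1, Fnip1, Klhl24, Paip2b and Hbp1, a transcriptional repressor. Without knockout replicate 1, edgeR called 1 gene, the pseudogene Gm15459.

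As a list, the genes of thyroid hormone production had a similar mean in both groups, while single members went both ways. The list of thyroid hormone synthesis and handling (19 genes tested) had a mean of 6.25 ± 0.11 log2 CPM in knockout and differed from control by 0.02 (95% permutation interval -0.15 to 0.20, exact permutation p = 0.786). Of its members 0 passed over all genes and 0 adjusted over the list alone, 10 had positive and 9 negative log2 differences, and camera gave an adjusted p of 0.902. Tg was at 210320 ± 42452 CPM in control and 180970 ± 15161 CPM in knockout, a log2 difference of -0.22 (SE 0.19), which was -0.12 without control replicate 4 and -0.34 with the adipocyte markers as a covariate. The log2 difference was -0.17 (SE 0.27) for Slc5a5, the iodide transporter. It was -0.31 without control replicate 2, -0.0184 without control replicate 3 and 0.10 with the immediate early genes as a covariate. For Tshr, the receptor of thyroid-stimulating hormone (TSH), it was 0.27 (SE 0.35), -0.0393 without knockout replicate 4 and -0.17 without replicate 4 of both groups. For Tpo, the peroxidase that iodinates Tg, it was -0.09 (SE 0.19), and from -0.18 to 0.0222 with each library left out. Slc26a7, an anion exchanger of the follicular cell, stood at -0.29 (SE 0.11), and the maturation factors of the dual oxidases, Duoxa1 and Duoxa2, at 0.26 (SE 0.12) and 0.23 (SE 0.11). Duoxa1 stood at 0.43 with the immediate early genes as a covariate.

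The transcription factors that define the thyroid cell did not pass either, as 6 tested members of that list gave 0 calls over all genes, 0 adjusted over the list alone and a camera adjusted p of 0.263. Pax8 differed by 0.16 (SE 0.11) and Foxe1 by 0.12 (SE 0.13) on the log2 scale. Pax8 stood at 0.0997 without knockout replicate 5 and 0.0898 with the immediate early genes as a covariate, and at most at 0.25 over all alternatives. Foxe1 stood at 0.0380 without knockout replicate 3, 0.0289 with the muscle markers, 0.0373 with the adipocyte markers and 0.0244 with 1 surrogate variable as a covariate. In the other direction it stood at 0.19 without knockout replicate 4 and at most at 0.26 over all alternatives. Nkx2-1 was at 362 ± 39.4 CPM in control and 362 ± 57.7 CPM in knockout, and its log2 difference ran from -0.0643 to 0.0822 with each library left out. Hoxa3, a patterning gene of the pharyngeal region, stood at 0.63 (SE 0.22), and at 0.36 with the immediate early genes as a covariate. The list of thyroid hormone receptors and response genes (12 tested) had a camera adjusted p of 0.692 and 0 calls, and Dio3, which inactivates thyroid hormone, was under 0.2 CPM in both groups. The list of thyroglobulin processing proteases (8 tested) had a camera adjusted p of 0.783.

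The retinoid genes were examined next, since Retsat acts in vitamin A metabolism. Dhrs3, a retinaldehyde reductase that is itself induced by retinoic acid, was at 90.2 ± 11 CPM in control and 129 ± 17.7 CPM in knockout (SD, n = 5 each), and the groups did not overlap. The log2 difference of Dhrs3 was 0.52 (SE 0.11). It was the only gene of the retinoid metabolism and transport list (32 tested) that passed adjusted over the list alone, and 0 passed over all genes (edgeR). Without control replicate 2 or 3 or knockout replicate 3 or 5, and with the muscle or adipocyte markers or 1 surrogate variable as a covariate, 0 passed adjusted over the list alone, while the log2 difference of Dhrs3 stayed between 0.43 and 0.60 in every alternative. In that list Cyp26a1, which degrades retinoic acid, stood at 0.64 (SE 0.27) from under 1 CPM (0.23 with the immediate early genes as a covariate), and Ces1d, a carboxylesterase, at -0.25 (SE 0.09). The list as a whole was not called (camera adjusted p = 0.692).

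Of the retinoic acid receptors and response genes (23 tested), Dhrs3 and Hoxa1 passed adjusted over the list alone and 0 passed over all genes. Hoxa1, a Hox gene induced directly by retinoic acid, was at 0.313 ± 0.052 and 0.572 ± 0.155 CPM, a log2 difference of 0.87 that was 0.51 with the immediate early genes as a covariate. Hoxb4 stood at 0.34 (SE 0.10) and Hoxa5 at 0.48 (SE 0.17) on the log2 scale. The camera test with its preset correlation called the list higher in knockout (adjusted p = 0.0292, with 15 members positive and 8 negative). With an estimated correlation the adjusted p = 0.529, and an exact permutation test of the list mean, which differed by 0.13, gave p = 0.103. The fry test for change in either direction called this list and no other (adjusted p = 0.00127). Camera's adjusted p was 0.0538, 0.0664 and 0.0611 without control replicates 1, 3 and 4 and 0.136 and 0.0694 without knockout replicates 3 and 5, with medians of 0.0425 to 0.0914 against 0.0620 in the main fit. It was 0.107 without the 2 libraries with high Pth counts, control 4 and knockout 4, and 0.649 with the immediate early genes as a covariate, where the median log2 difference was -0.0279 (both chosen after the data were seen). Adjusted over the list alone, 1 gene passed without control replicate 1, 3, 4 or 5, without knockout replicate 3, 4 or 5, without a filter, with a mean CPM of at least 1 and without the 2 libraries with high Pth counts. It was 0 genes with the adipocyte markers as a covariate and 5 with scaling by library totals.

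Immediate early genes, which respond within minutes to growth factors, hormones or stress, were higher in knockout. Their mean over 28 tested members was 3.67 ± 0.19 log2 CPM in control and 4.24 ± 0.39 in knockout (SD over 5 libraries each). The difference of 0.57 (95% permutation interval 0.14 to 1.07) had an exact permutation p = 0.0079, unadjusted, and the groups did not overlap. Over the 38 lists tested, 0 passed this permutation test after Benjamini-Hochberg adjustment. The adjusted permutation p of the immediate early genes was 0.302. Their unadjusted p is the smallest that 5 against 5 libraries allow, so 1 list alone could not have passed. Of the members, 25 had positive log2 differences, 9 passed adjusted over the list alone and 0 passed over all genes. Nr4a3, an orphan nuclear receptor, was at 4.05 ± 1.20 CPM in control and 15.8 ± 10.4 CPM in knockout, and Fos at 4.38 ± 1.57 and 17.5 ± 20.9 CPM. The log2 differences were 1.97 (SE 0.43) for Nr4a3, 2.00 (SE 0.60) for Fos, 1.43 (SE 0.43) for Arc and 0.64 (SE 0.18) for Dusp1. That of Fos was 0.91 without knockout replicate 4 and 0.78 without both libraries with high Pth counts. Camera called the list (adjusted p = 2.72e-12), and with an estimated correlation its adjusted p = 0.452. The count of 9 members fell to 0 without control replicate 4 or knockout replicate 3, to 1 without control replicate 3 or knockout replicate 4, to 2 without control replicate 1 and to 3 without control replicate 2. It was 0 without both libraries with high Pth counts, with limma-voom and with the adipocyte markers as a covariate, and 5 with robust empirical Bayes. The list median of 0.47 was 0.35, 0.40 and 0.40 in the first 3 of these fits, and camera called the list in each.

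The list of TSH and cAMP response genes (28 tested) was not called by camera (adjusted p = 0.784). Adjusted over the list alone 4 members passed, of which Fos and Dusp1 are also immediate early genes, and 0 passed over all genes. The others were Areg, an EGF receptor ligand, at 1.12 ± 0.478 CPM in control and 7.85 ± 9.20 CPM in knockout, and Irs1, the insulin receptor substrate, at 8.94 ± 2.38 and 5.56 ± 1.36 CPM. That count was 0 without control replicate 1, 2, 3 or 4, without knockout replicate 1, 3 or 4 and without both libraries with high Pth counts, and 1 without control replicate 5. It was also 0 with limma-voom, with robust empirical Bayes, with a mean CPM of at least 1 and with the muscle or adipocyte markers as a covariate. Over all alternatives the log2 difference ran from 1.88 to 3.08 for Areg and from -0.87 to -0.51 for Irs1.

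Among metabolic lists, camera called 3 lower in knockout. In ChREBP targets and lipid synthesis (26 tested, adjusted p = 0.00108, and adjusted p = 0.529 with an estimated correlation), 20 members were negative, 0 passed over all genes and Lpin1 passed adjusted over the list alone. Lpin1, a phosphatidate phosphatase, was at 76.9 ± 9.88 CPM in control and 55.4 ± 8.90 CPM in knockout. That call over the list alone was absent without any of the libraries except knockout replicate 5, whose removal gave 2 genes. It was absent too with library totals, with a mean CPM of at least 1 and with the muscle or adipocyte markers or 1 surrogate variable as a covariate, while the log2 difference of Lpin1 stayed between -0.58 and -0.37 in every alternative. Gpd1, Gpam and Scd1 stood at -0.41 (SE 0.12), -0.45 (SE 0.17) and -0.37 (SE 0.16) on the log2 scale, Gpam at -0.27 without control replicate 5 and -0.29 with 1 surrogate variable, and Scd1 at -0.21 with the immediate early genes as a covariate. In fatty acid oxidation and PPAR targets (37 tested, camera adjusted p = 0.00176, and adjusted p = 0.762 with an estimated correlation), 27 members were negative and 0 passed adjusted over the list alone. Hadha, of the mitochondrial trifunctional protein, stood at -0.25 (SE 0.08), Acadvl at -0.33 (SE 0.11) and the coactivator Ppargc1a at -0.43 (SE 0.14). Acadvl stood at -0.20 with the adipocyte markers and -0.21 with the immediate early genes as a covariate. The member with the smallest p went the other way: Cyp4a14, a fatty acid hydroxylase, stood at 3.49 (SE 1.07) from under 1 CPM in both groups. In hypoxia and glycolysis (28 tested, camera adjusted p = 0.0292, and adjusted p = 0.529 with an estimated correlation), 21 members were negative, with Hk2 at -0.62 (SE 0.27) and Pdk1 at -0.31 (SE 0.14). Hk2 stood at -0.29 with the muscle markers, -0.38 with the adipocyte markers and -0.26 with 1 surrogate variable, and Pdk1 at -0.18 without the 2 libraries with high Pth counts. The mitochondrial respiratory chain, in which Sdha stood at -0.24 (SE 0.07) and Ndufs1 at -0.29 (SE 0.09), was not called (camera adjusted p = 0.051). The exact permutation p of the list means was 0.206, 0.516 and 0.254 for the 3 called lists. Camera no longer called lipid synthesis without control replicate 3 (adjusted p = 0.0506) or fatty acid oxidation without knockout replicate 3 (0.0813) or without the 2 libraries with high Pth counts (0.273). It no longer called hypoxia and glycolysis without control replicate 1 (0.0516) or 5 (0.139) or knockout replicate 3 (0.129) or 5 (0.0883). With each library left out, the median of hypoxia and glycolysis stayed negative, from -0.13 to -0.063. That of fatty acid oxidation was -0.11 without knockout replicate 3, against -0.13 in the main fit. Camera's adjusted p for hypoxia and glycolysis was 0.0736 with scaling by library totals. Its median of 0.0224 there came with a shift of all genes, whose median was 0.0947 with library totals against 0.0076 in the main fit. It was 0.231 with the muscle markers, 0.130 with the adipocyte markers, 0.118 with the immediate early genes and 0.289 with 1 surrogate variable as a covariate, with medians of -0.0634, -0.0864, -0.0934 and -0.0710 against -0.0714 in the main fit. For fatty acid oxidation it was 0.473 with the adipocyte markers, some of which are members of that list too. With the immediate early genes it was 0.659, and the median was 0.0345.

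Markers of tissues next to or within the thyroid differed strongly between libraries of the same group. The mean of the skeletal muscle markers ran from 0.77 to 7.19 log2 CPM in control and from 0.60 to 5.07 in knockout, and the first principal component (28.5% of the variance) had 29 of them among its 100 leading genes. Camera called this list lower in knockout with all 41 members negative (adjusted p = 3.05e-15, and adjusted p = 0.529 with an estimated correlation), while the exact permutation p was 0.270 and 0 members passed adjusted over the list alone. Myh8 and Myl3, myosin genes, stood at -4.02 (SE 1.11) and -2.42 (SE 0.94), and at -2.05 and -1.56 without control replicate 2, and Myh8 at -1.93 with the adipocyte markers as a covariate. The list's median of -2.16 was -0.83 without control replicate 5, and with 1 surrogate variable it was 0.13 and the call was lost (adjusted p = 0.365). The thymus and T cell list was at 2.46 log2 CPM in control replicate 3 and at most 0.16 in every other library. Camera called it lower (adjusted p = 0.000476, and adjusted p = 0.835 with an estimated correlation), but its adjusted p was 0.561 without control replicate 3 and 0.831 with the immediate early genes as a covariate. Its leading gene Cd8a was at 2.49 ± 4.78 CPM in control and 0.288 ± 0.130 CPM in knockout, and Trbc2 at 2.14 ± 4.19 and 0.289 ± 0.105 CPM. Without control replicate 3 the log2 differences of Cd8a and Trbc2 were -0.29 and 0.12, against -3.11 and -2.88 in the main fit and -1.34 and -0.90 with limma-voom. Parathyroid markers stood at 8.09 log2 CPM in control replicate 4 and 7.74 in knockout replicate 4, against at most 3.12 elsewhere.

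Camera also called brown adipocyte markers lower (adjusted p = 3.79e-05, and adjusted p = 0.529 with an estimated correlation), with Pank1 at -0.47 (SE 0.14) and Cpt1b at -0.78 (SE 0.32), 14 of 16 members negative and 0 passing adjusted over the list alone. With the immediate early genes as a covariate the adjusted p of the brown adipocyte list was 0.551, its median went from -0.27 to -0.0138, and Pank1 stood at -0.28 and Cpt1b at -0.49. Cpt1b stood at -0.46 with the muscle markers, -0.41 with the adipocyte markers and -0.46 with 1 surrogate variable. It is itself among the adipocyte markers, so part of its change with them is built in. Endothelial markers were called higher (adjusted p = 2.05e-06, and adjusted p = 0.529 with an estimated correlation), with 21 of 23 members positive and 0 passing adjusted over the list alone. Emcn, Robo4 and Plvap, genes of the vessel wall, stood at 0.45 (SE 0.19), 0.33 (SE 0.13) and 0.35 (SE 0.16). Red blood cell markers were called higher (adjusted p = 0.000818, and adjusted p = 0.529 with an estimated correlation), with Snca at 0.87 (SE 0.31), Gypa at 1.18 (SE 0.44), Alas2 at 0.82 (SE 0.31), and Hba-a1 at 37.2 ± 8.94 and 64.9 ± 35.8 CPM. Without knockout replicate 4 the log2 differences were 0.51 for Snca, 0.75 for Gypa, 0.47 for Alas2 and 0.41 for Hba-a1, and the list median was 0.39 instead of 0.80 with the call kept (adjusted p = 0.0345). With the immediate early genes as a covariate the call was lost (adjusted p = 0.0544) at a median of 0.61. The endothelial median of 0.27 was 0.15 without knockout replicate 1 and at most 0.41 over all alternatives. With the preset correlation the endothelial call was kept in each of them. The exact permutation p was 0.103 for brown adipocyte, 0.135 for endothelial and 0.0873 for red blood cell markers.

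**Figure D2:**
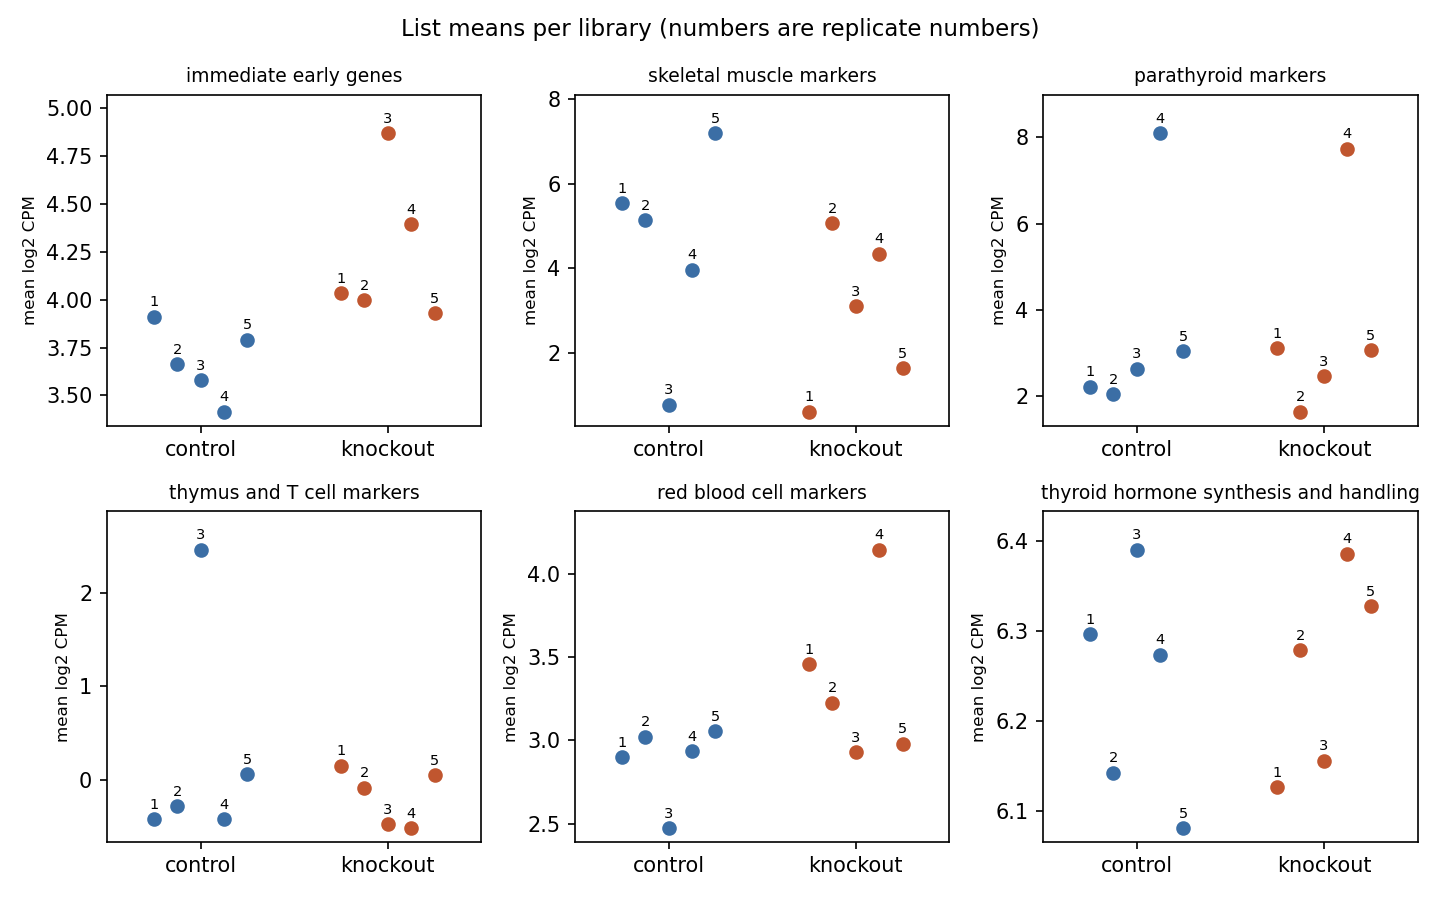
Mean log2 CPM of 6 gene lists in each library, with the replicate number beside each point and the groups on the horizontal axis. Parathyroid markers are high in replicate 4 of both groups, thymus and T cell markers are high in control replicate 3 (2.46), and immediate early genes do not overlap between groups.

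In all, camera with its preset correlation called 10 of 38 lists, 4 higher and 6 lower in knockout, and none of these calls held with an estimated correlation or in the directional fry test, each of which called 0 lists. Camera called 18 lists without control replicate 2, 17 without knockout replicate 4, 16 with the adipocyte markers as a covariate and 6 with the immediate early genes as one. For the 28 lists not called, camera's adjusted p ran from 0.051 to 0.96. These were the lists named above as not called and those of cell cycle (0.051), pericytes and smooth muscle (0.0786), granulocytes and mast cells (0.0786), salivary gland (0.0824), B and plasma cells (0.121), interferon response (0.138), cholesterol synthesis (0.211), cartilage (0.211), extracellular matrix (0.244), macrophages and dendritic cells (0.357), white adipocytes (0.377), C cells (0.457), follicular epithelium and cilia (0.692), the unfolded protein response (0.692), Schwann cells and neurons (0.692), parathyroid (0.753), airway epithelium (0.846), MHC class II (0.902), ferroptosis (0.907), NRF2 and antioxidant defence (0.907) and fibroblasts (0.96). The sign of the mean, the median and the test differed for thyroid hormone synthesis, thyroid hormone response, retinoid metabolism, TSH and cAMP, airway epithelium, ferroptosis and fibroblasts, all of them not called.

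**Figure D3:**
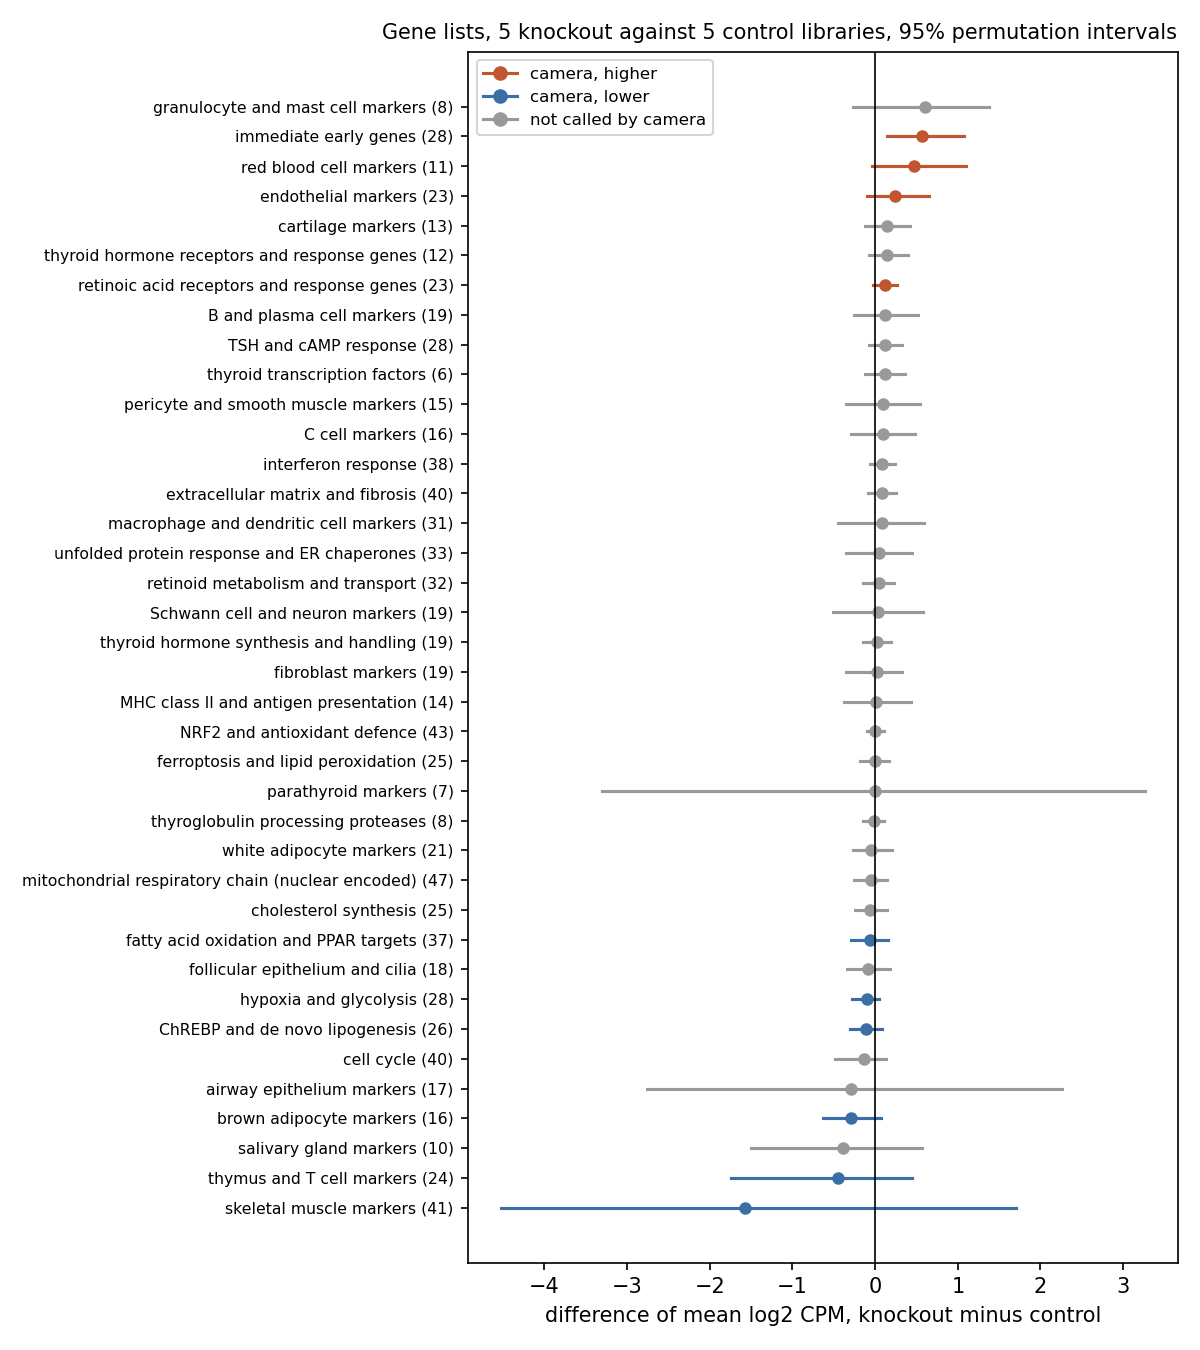
Difference of the mean log2 CPM between knockout and control for each of 38 gene lists (number of tested genes in parentheses), with 95% permutation intervals as lines. Orange and blue mark lists that camera called higher or lower with its preset correlation; the interval of the immediate early genes runs from 0.14 to 1.07 and those of the other called lists include 0.

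Genes close to Retsat on chromosome 6 were examined because a targeted allele can carry neighbouring DNA with it. Of 53 other tested genes within 5 Mb, 0 passed the adjusted threshold in edgeR. At an unadjusted p under 0.05 there were 8 (15.1%), against 7.64% of the remaining genes (Fisher's exact test, two-sided p = 0.0619). Within 20 Mb there were 33 of 288 (11.5%, against 7.60%, Fisher's exact test p = 0.0188), and again 0 passed the adjusted threshold. Fisher's test takes genes as independent, which genes in tissue are not. Both windows hold Cd8a and Cd8b1, T cell genes whose counts were high in control replicate 3. Of the other genes named, Paip2b, Klf15, Snca and Hk2 lie in the wider window. Both groups carried the floxed alleles, so DNA carried with the allele is not expected to differ between them. Whether DNA in that window differed between the groups for another reason was not tested.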

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

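In each group of 5 libraries the gap between the highest or lowest log2 value and its neighbour was divided by the group's range and set against Dixon's critical value. Over 210 groups of values (64 genes, 38 lists and 3 library measures), 17 passed where chance gives about 10.5. All 3 tests weighed here for Gm15459 were chosen after its values were seen.

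Control replicate 3 was far from the other control libraries in Cd8a (ratio 0.866), Cd8b1 (0.729), Trbc2 (0.867) and the thymus and T cell list (0.833), each at its highest, and in Slc26a7 (0.767) and Hoxa3 (0.852), also at its highest. It was the lowest in Hba-a1 (0.793) and in the red blood cell list (0.728). Control replicate 4 was the highest in Retsat (0.803) and the parathyroid list (0.836) and the lowest in Dhrs3 (0.865). Knockout replicate 4 was the highest in the parathyroid list (0.759) and in Fos (0.714). Control replicate 2 was the highest in Paip2b (0.888), control replicate 5 in Gpam (0.752), and knockout replicate 2 in the B and plasma cell list (0.722).

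Gm15459, a processed pseudogene on chromosome 5 (5831615 to 5833555), was at 4.01 CPM in knockout replicate 1 and between 66.7 and 112 CPM in the other 4 knockout libraries (ratio 0.843), against 2.85 ± 0.453 CPM in control (SD, n = 5). Activation of its surroundings is argued against, since 0 of 7 other tested genes within 1 Mb were higher in knockout at an unadjusted p under 0.05. Its transcript is 99.742% identical to that of Hspa8, a chaperone gene on chromosome 9 with a mean of 701 CPM, so a few bases decide where a read is placed and reads of Hspa8 could be counted there. The mean of Hspa8 was 731 CPM in control and 672 CPM in knockout. Other pseudogenes are close copies too, 2 of them 98.7% and 98.6% identical over the whole length and 1 of these within 5 Mb of Retsat, but both were under 1 CPM in each group. A long noncoding RNA identical over 95.6% of the length is annotated on the other strand of the same place. A sequence variant in Hspa8 would shift such reads, and linked DNA of another strain is a candidate source: 12 of 400 tested genes within 20 Mb of Hspa8 (3.0%) had an unadjusted p under 0.01, against 1.26% of the others (Fisher's exact p = 0.0062). That test takes genes as independent, which genes in tissue are not, and its cut-off of 0.01 differs from the 0.05 used around Retsat. Reads were not at hand to look for a variant in Hspa8, so linked DNA of another strain stays a hypothesis.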

How the results depend on the processing

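The fits without the 2 libraries with high Pth counts, without Tg and the mitochondrial genome and with the immediate early gene covariate were chosen after the data were seen. The mean of the immediate early genes did not overlap between groups, so that covariate can take up part of a group difference. Retsat kept its direction and an unadjusted p under 0.05 in all 24 alternatives, from -1.0 to -0.82 with each library left out and -0.60 with the immediate early gene covariate. The count of genes past the threshold was 0 except for 14 with DESeq2, and it ran from 0 to 1 with each library left out, the 1 being Gm15459 without knockout replicate 1. Camera's count of lists was 16 with the adipocyte covariate, 6 with the immediate early gene covariate, 0 with an estimated correlation, 0 with fry and from 8 to 18 with each library left out. Near Retsat, 8 genes had an unadjusted p under 0.05 where 0 passed the adjusted one. With the replicate block 0 genes passed and camera called 11 lists, not among them hypoxia and glycolysis (adjusted p = 0.0586), and adjusted over the list alone 0 TSH and cAMP, 1 retinoic acid, 2 ChREBP and 5 immediate early genes passed; the numbers were not read as pairs, since same-number correlations ran from -0.21 to 0.31 and 2 of 5 control libraries correlated best with their own number.

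Of 1492 values of 63 other named genes, 17 changed sign, and 8 passed the threshold that had not. In units of log2, Nkx2-1 was 0.0917 with library totals, 7.1e-05 with a mean CPM of at least 1, 0.0152 with the adipocyte covariate, 0.0928 without the 2 libraries with high Pth counts and -0.0643 to 0.0822 with each library left out. Tpo was 0.0017 with library totals and -0.184 to 0.0222 with each library left out, Tshr -0.17 without the 2 libraries with high Pth counts and -0.0393 to 0.516 with each library left out, Slc5a5 0.10 with the immediate early gene covariate, Trbc2 -3.18 to 0.117 and Cd8b1 -3.52 to 0.33 with each library left out. Of 227 values of the 10 called lists, 24 lost the call and 3 more changed direction in the test as well. In those 3 the list median was 0.0345 for fatty acid oxidation with the immediate early gene covariate, 0.13 for skeletal muscle with 1 surrogate variable and -1.05 to 0.0994 for thymus and T cells with each library left out. Of the 24, the median changed sign too for hypoxia and glycolysis with library totals (0.0224) and for the retinoic acid list with the immediate early gene covariate (-0.0279). The sign changes without 1 or 2 libraries follow from those libraries. Those with library totals come from a shift of all genes, whose median log2 difference was 0.0076 with TMM and 0.0947 with library totals. The cause of the others was not tested. At this spread a change of 1.5-fold was recovered in 20% of simulated genes, so changes of that size can be missed. In that simulation many genes changed at once, so where few genes change, larger changes can be missed more often than it shows.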

Other observations

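The heat shock, FOXO and clock lists were written after the leading genes were seen and before their own values were; the test of TSH and cAMP genes was chosen after the list's values were seen, as were the FOXO tests that leave genes out, and the gene names in the next paragraph after theirs.

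Several genes known as targets of FOXO transcription factors, which act when insulin signalling is low, stood lower in knockout beside Klhl24, Fnip1, Lpin1 and Hbp1. Hbp1, a transcriptional repressor of the cell cycle, was at 70.9 ± 11.7 CPM in control and 47.7 ± 6.17 CPM in knockout. Klf15 was at 22.0 ± 4.57 and 14.8 ± 3.35 CPM, Rragd at 186 ± 20.7 and 144 ± 18.2 CPM, Pik3ip1 at 128 ± 28.1 and 88.0 ± 22.9 CPM, and Ccng2 at 31.7 ± 3.12 and 24.4 ± 4.59 CPM (SD, n = 5 each). None passed over all genes in edgeR (adjusted p = 0.634 for each), while DESeq2 called Hbp1 (adjusted p = 0.0282). With the immediate early genes as a covariate, the log2 difference of Pik3ip1 went from -0.54 to -0.26 and that of Ccng2 from -0.38 to -0.23. The hypothesis of lower FOXO target expression was tested on a list of 30 genes that leaves out the 4 leading genes, and its mean differed by -0.21 (95% permutation interval -0.40 to -0.01, exact permutation p = 0.0476, and 0.190 adjusted over the 4 lists and differences tested here). The leading genes that prompted it came from the same 10 libraries, and some members also belong to the planned lists. The test is therefore not independent of those observations. Of the 30, 23 had negative and 7 positive log2 differences, and 6 had an unadjusted p under 0.05, all of them negative. Klf15, Rragd, Pik3ip1 and Ccng2 were the 4 members with the smallest p. Without Trim63 and Fbxo32, which muscle also expresses, the difference was -0.15 (exact permutation p = 0.0397). Klf15 lies within 20 Mb of Retsat, and without the list's genes in that window the difference was -0.22 (exact permutation p = 0.0476). The means of the skeletal muscle and brown adipocyte markers moved the same way, by -1.57 and -0.29. Leaving out Trim63 and Fbxo32 does not remove what muscle adds through other members. What attached muscle or adipose tissue adds to the FOXO list was not tested. A different time of day at dissection stays open. The distance between the Per and Rev-erb arm and the Bmal1 arm of the clock differed by -0.79 between groups, with an interval of -2.20 to 0.85 (exact permutation p = 0.262). In the Per and Rev-erb arm, 8 of 9 members had negative log2 differences. In the Bmal1 arm, 3 members were positive and 2 negative. Nr1d1 was at 226 ± 26.7 and 155 ± 38.2 CPM and Nr1d2 at 165 ± 24.8 and 113 ± 37.8 CPM, with log2 differences of -0.54 each that were -0.12 and -0.23 with the immediate early gene covariate. A hypothesis that insulin or feeding state differed may be worth a test in other samples.

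The 38 list tests, as counts, cannot exclude chance. Of 100 splits of the 10 libraries, 88 gave at least the 10 lists of the real split, and the highest other split gave 22. The median of the other splits was 13 lists. Camera's adjusted p-values with the preset correlation, however small, are therefore not evidence against chance by themselves. The estimated correlation, with which 0 lists were called in the real split, was not run on the other splits. Why so many splits call lists was not tested. For genes at an unadjusted p under 0.05, 15 of 100 splits gave at least the real 1484, with 2362 as the highest other, so chance is not excluded there either. For genes past the threshold the real count of 0 leaves nothing to test, and the highest other split gave 2.

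The immediate early genes did not overlap between groups, and 2 explanations stay open. Camera's call of this list does not by itself exclude chance, since 52 of 100 splits put the list past the threshold and 5 of them, the real one included, gave an adjusted p as small. Stress during dissection could raise them, and the heat shock list, which would be higher too, differed by 0.0816 (95% permutation interval -0.16 to 0.34, exact permutation p = 0.460). Of its 17 members, 11 had positive and 6 negative log2 differences, and 2 had an unadjusted edgeR p under 0.05, both positive. Stronger TSH and cAMP signalling could also raise the immediate early genes. The 25 tested TSH and cAMP genes that are not immediate early genes differed by 0.0032 (interval -0.14 to 0.15, exact permutation p = 0.984). Neither test decides. The first interval includes 0 and a larger difference. The second interval ends at 0.15, below the 0.57 by which the immediate early genes differed, so the mean of that list did not rise as much. Its difference was not at or below 0, which the rule against this explanation required, and its members move both ways. An effect of Retsat loss was not tested apart from these.

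The fatty acid oxidation list was called lower by camera, at a median log2 difference of -0.13, but its exact permutation p of 0.516 gives no reason to exclude chance. Attached skeletal muscle could lower it: with the muscle markers as a covariate the median was -0.10, which is 81.2% of its size (95% bootstrap interval over members 42.3% to 110%), and camera's call stood (adjusted p = 0.0376). Attached adipose tissue could too: with the adipocyte markers it was -0.0529, or 41.1% (interval -27.0% to 71.1%), and the call was lost (adjusted p = 0.473). Some of those markers, Ppargc1a and Cpt1b among them, are members of the fatty acid oxidation list too, so part of that shrinkage is built in. Both explanations remain open, as the share kept is too uncertain to tell. The intervals resample members of the list, not libraries, so they do not measure the spread between libraries. The muscle values met the rule written beforehand against that cause. A further demand, that the whole interval meet it, was added in the test and was not met.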
